A study of Drosophila melanogaster with 3 samples.

How the data were processed

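In all, 3 genomic DNA microarrays were analysed, all of 1 group. Each array compared, in 2 channels, DNA from the larval salivary glands of 2 Drosophila strains. The Su(UR)- strain is mutant for Su(UR), the gene for Suppressor of Underreplication, and the other strain has 4 doses of Su(UR)+. The labels do not say how much of the gene's DNA the Su(UR)- strain keeps. Salivary gland cells copy their DNA many times without dividing, and some chromosome regions are copied less often than the rest. The labels do not say whether the 3 arrays came from separate groups of larvae, so the p-values measure the spread between these arrays, which may be technical.

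The authors' deposited table gives 1 log ratio per spot and array, taken here as log2, with any normalization by the authors not stated. The log base is not given in the sources used here. Values beyond what log10 ratios of a 16-bit scanner could reach lay on 69, 61 and 46 spots of arrays 1, 2 and 3, but the range of a natural log was exceeded by 1 spot only, at 16.15, which is also just beyond the log2 range. Were the base another, sizes and counts past a fold limit would change, while signs and tests against 0 would not. Background correction, normalization, spot filter, dyes and the direction of the ratio are also not given in the sources used here. No signal or background column was used, so precision is limited by the number of arrays and the brightness behind each ratio is unknown. Values were present for 39296, 40501 and 35541 of 47616 spots on arrays 1, 2 and 3, with array medians of -0.028, -0.028 and -0.076.

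Every array was centred on the median of its spots, without loess or quantile normalization. The 2 spots of each probe, which lie a fixed number of rows apart in the table, were averaged, then the probes of a gene; all 23808 spot pairs carried 1 annotation. Spots of a pair correlated with Pearson r of 0.69, 0.74 and 0.821 on arrays 1, 2 and 3. The platform annotation named 1 gene for 26910 spots and several for 306, which were not used; 20400 spots had no annotation row and are unnamed here. Of 11610 genes, 11138 were matched to the reference gene table by Entrez identifier and 68 by accession, and 404 kept the file's name. Symbols changed for 71 genes. Of the 10055 genes with a value on all 3 arrays, 9715 had a place on a chromosome arm. Among 966 genes with at least 2 complete probes, 47 had probes that differed by more than 1 on the log2 scale. The reference table, of assembly Release 6, served for names, arms and gene order only, since the sources used here name no build for the probes.

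Genes were tested against a ratio of 0 with limma 3.58.1 in R 4.3.3 (intercept fit, moderated statistic, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). With 3 arrays an exact sign-flip test cannot give a p below 0.25, so calls rest on the variance shared across genes. Regions were called from the median of 9 adjacent genes, at the threshold where 1000 shuffles of gene order within arms gave at most 5% of the observed windows; windows were merged, and a region was kept if its mean had 1 sign on all 3 arrays. The correlation of adjacent genes was tested with 100000 shuffles. Of 21 gene lists, the 16 with at least 3 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation. They were also tested with fry and by 10000 rotations of the list along the arms. The arms were joined end to end, so members could pass to another arm. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

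Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 15 genes of largest absolute mean in each direction that passed the test with 1 sign on all arrays, up to 4 examples per list, and the first, last and most extreme genes of the 5 regions with the highest and the 12 with the lowest median. The 2 checks fixed for the direction of the ratio were the SuUR gene and the bithorax complex. No bithorax gene on the list had a measured named probe, so the second check could not be run as fixed, and sizes and counts are given by the sign of the deposited ratio.

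The gene test, camera with a preset correlation, the region calls and the correlation of adjacent genes were tested on simulated data. The other tests were not. Among 10055 genes, 58% of those raised by 1.5-fold and 78% of those raised by 2-fold were recovered, as were 48% and 84% of those lowered by as much, with 2.9% of calls false. All 30 regions planted among 9715 genes, each of 16 genes raised by 0.6, were found, with 0 called elsewhere. Most regions called in the data had lower means, and smaller rises were not planted. The simulated genes had independent noise around 0, and for regions the gene means were limited in range and shuffled. Neither simulation held a trend along the printing order, so these rates do not cover errors from print position. Alternatives covered centring, scaling between arrays, averaging, missing values, each array left out, the test and fold limit, the window and the list tests. Centring on named spots, removing a trend along the table's printing order and leaving out list members of another gene family were added after the data were seen.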

Results

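The data were 3 two-channel arrays comparing salivary gland DNA of Su(UR)- larvae and of larvae with 4 doses of Su(UR)+, as 1 log ratio per spot, taken as log2. The comparison asks which parts of the genome differ in copy number between larvae mutant for the gene and larvae with it in excess. Pearson correlations between arrays across 10055 genes were 0.703, 0.684 and 0.709, and Spearman correlations 0.631, 0.589 and 0.648; genes are not independent replicates. In all, 64.4% of genes had 1 sign on all 3 arrays, against 31.7% expected from the share of positive genes on each array. With each array centred on its median gene, 59.5% did so. Values are mean log2 ratios ± SD over n = 3 arrays, relative to each array's median, and the median gene lay at -0.094.

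The SuUR gene itself, whose dose sets the 2 strains apart, had a ratio of -1.69 ± 0.19 (limma adjusted p = 0.00441), negative on all 3 arrays. The adjacent gene CG6310, looked at after the values were seen, had -1.26 ± 0.46, while Mocs1 beyond it had 0.06 ± 0.05 and CG32075 on the other side of SuUR -0.07 ± 0.21. The next genes, Pfdn2 and CG32069, had -0.33 ± 0.03 and -0.21 ± 0.08, negative on all 3 arrays. None of Ubx, abd-A and Abd-B had a value under its name on all 3 arrays, and values on fewer arrays were not looked up. CG31275, which lies between Ubx and abd-A in gene order and was chosen after its values were seen, had 1.80 ± 0.29 (SD, n = 2) with no value on array 3. Positive ratios below are those of opposite sign to SuUR.

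The positive ratios were clustered along the chromosomes. Among the 15 genes with the most positive ratios, 12 lay in regions where neighbouring genes were positive too. They included CadN, a neuronal cadherin (2.36 ± 0.18), beat-Ia, an axon guidance protein (2.44 ± 0.39), BicC, an RNA-binding protein of oogenesis (2.33 ± 0.16), Sytalpha, a synaptotagmin (2.26 ± 0.02), and t-Grip128, a testis gamma-tubulin ring protein (2.59 ± 0.61). The others in regions were CG2750 (2.70 ± 0.44), CG31784 (2.61 ± 0.16), CG11227 (2.61 ± 0.50), I-3 (2.37 ± 0.20), CG1314 (2.33 ± 0.29), CG4650 (2.25 ± 0.11) and CG4891 (2.24 ± 0.12). Outside regions lay Cyp6a17, a cytochrome P450 (2.85 ± 0.18), Marf1, a regulator of meiosis (2.75 ± 0.04), and CG40006 (2.20 ± 0.31). The adjusted p of these 15 genes ranged up to 0.0117.

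Among the 15 genes with the most negative ratios, 1 lay in a called region, of positive ratio. This was CG3294, which had -3.19 ± 0.27 although its 4 flanking genes had a median of 0.75. Of the 14 with a place on an arm, 7 had flanking genes with a median at or below -0.29, the lowest being -0.86 around HnRNP-K. Rme-8, an endocytic chaperone, had -2.61 ± 0.34, yellow-e2 -2.53 ± 0.38, krimp, a piRNA pathway protein, -2.42 ± 0.48, and bowl, a zinc finger transcription factor, -1.75 ± 0.05. Nle (-2.53 ± 1.21), HnRNP-K (-2.48 ± 1.08), Klp67A, a kinesin (-2.27 ± 1.04), and Uch (-2.06 ± 0.96) varied most between arrays. The remaining genes were Reph (-2.44 ± 0.69), CG33013 (-2.13 ± 0.17), jagn (-1.98 ± 0.51), CtsL4 (-1.73 ± 0.28), CG7227 (-1.69 ± 0.67) and SuUR.

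In total, 601 genes had a positive and 885 a negative ratio past the adjusted threshold, of which 352 and 231 were at least 1.5-fold and 147 and 65 at least 2-fold. Positive calls made up 40.4% of all calls, but 25% without centring, 54.3% with centring on the mode, 61.8% with centring on named spots and 73.5% after a trend along the printing order was removed. Without arrays 1, 2 and 3 in turn, 269, 130 and 293 positive and 121, 40 and 265 negative calls were left.

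**Figure D1:**
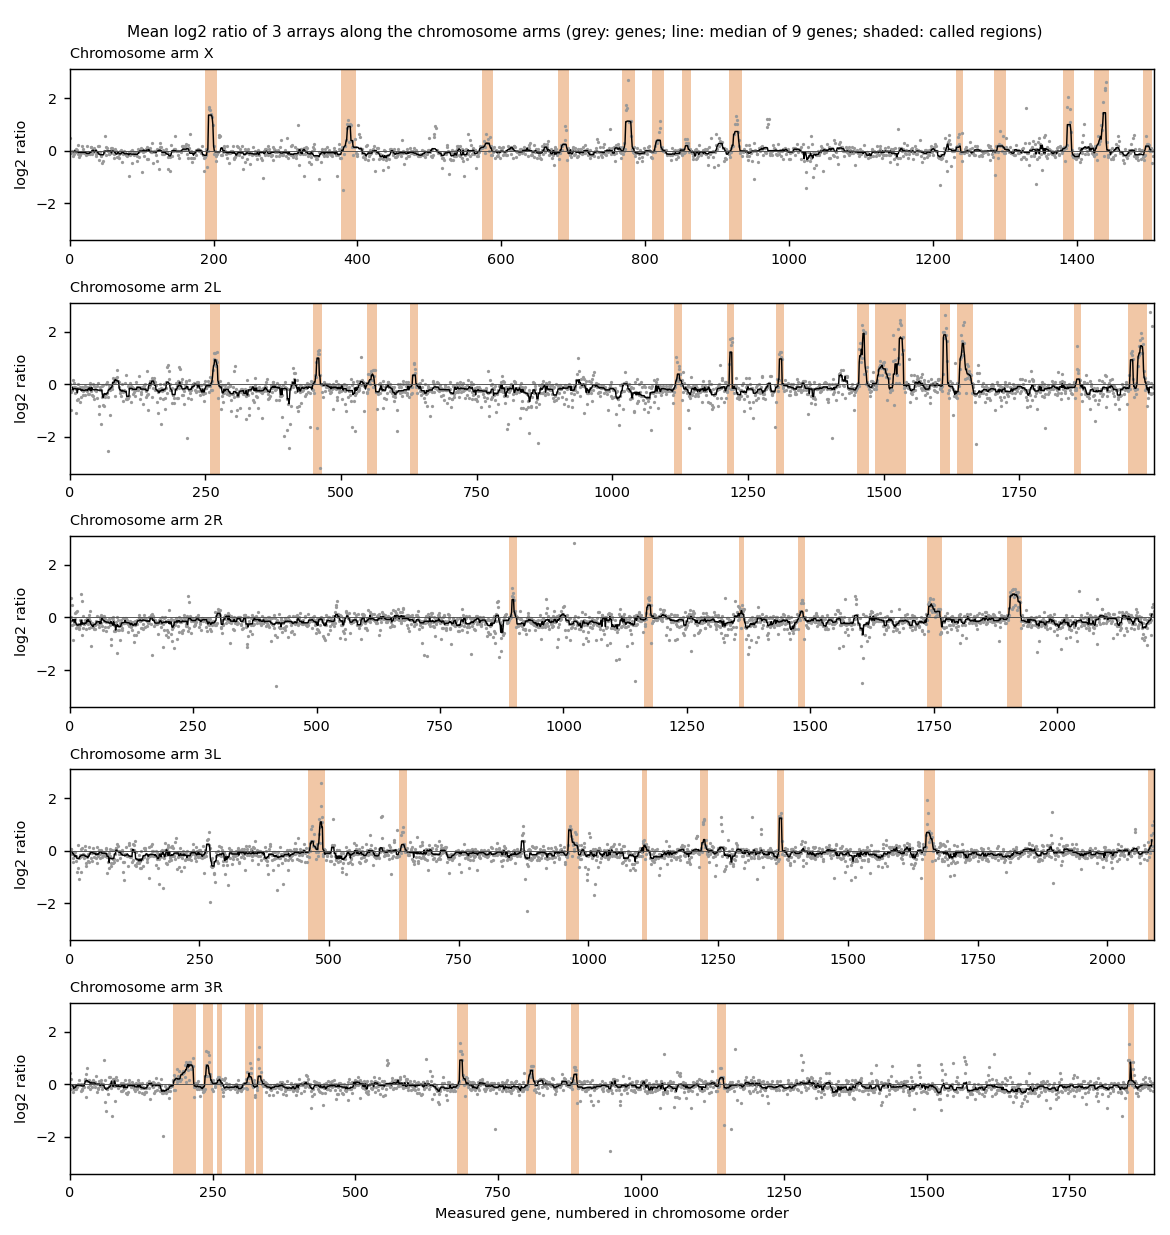
Mean log2 ratio of 3 arrays for every measured gene (grey points) in chromosome order on 5 arms, with the median of 9 adjacent genes (line) and the 50 called regions (shaded). In each shaded region the median line reaches the threshold for regions, and no region of negative ratio was called.

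Neighbouring genes had similar ratios: the correlation of adjacent genes was 0.426 (permutation p = 1e-05, the smallest that 100000 shuffles can give; two-sided), against at most 0.071 in shuffled order. It was 0.344, 0.227 and 0.079 for genes 2, 5 and 10 places apart. In all, 50 regions of positive ratio were called, with 923 genes and 9 to 56 genes each, where 533 windows passed against 23.6 expected from shuffled order. No region of negative ratio was called (0 regions). At an unadjusted p under 0.05, limma counted 2833 single genes with a negative ratio and 1102 with a positive one. That test is against 0 while the median gene lay at -0.094, so this split depends on the centring. Of the genes at least 1.5-fold positive on the arms, 249 of 333 (74.8%) lay in regions, against 8 of 226 (3.5%) of those at least 1.5-fold negative and 9.5% of all genes. Regions were called from the same ratios, so this difference is partly built in. With the gene itself left out, 75.1% of these positive genes had 4 flanking genes with a median of at least 0.29, against 5.4% of all genes.

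The region with the highest median ran from noc to THG on 2L, with 22 genes, a mean of 0.84 ± 0.03 and its most positive gene CG4650. The region from Spn100A to CG31007 on 3R had 10 genes and a mean of 0.59 ± 0.05, led by CG31010 (1.51 ± 0.32). The region from CG9877 to CG9875 on 2R had 31 genes and a mean of 0.53 ± 0.13, led by RpL22-like, a ribosomal protein paralogue (1.09 ± 0.10). The region from Cyp312a1 to not on 3L, which holds the cell death genes grim and skl, had 21 genes and a mean of 0.48 ± 0.04, led by CG5103 (1.92 ± 0.13). The region from Lsm12a to CG42258 on X had 18 genes and a mean of 0.74 ± 0.13, led by CG2750. Chosen after their values were seen, the longest region, from yuri to CG4935 on 2L, had 56 genes and a mean of 0.56 ± 0.08, the region from qua to Grl36b with CadN had 0.59 ± 0.13, and the region at the base of 2L, from dimm to Clamp, had 0.52 ± 0.01. By arm, 13 regions lay on X, 13 on 2L, 6 on 2R, 8 on 3L, 10 on 3R and 0 on chromosome 4.

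The 12 regions with the lowest medians, from -0.06 to 0.10, ran from NijC to CG14384, AOX1 to c(3)G (both 3R), lncRNA:CR32553 to CrebB, Bcat to CG32631, S6kII to CG17167 (all X), CG10063 to BBS1, CG32147 to CG7857 (both 3L), prod to CG15118 (2R), and spict to mTor, tctn to CG9498, Pyroxd1 to CG10947 and spz4 to Tsp33B (all 2L). Their most positive genes included CG4988 (1.77 ± 0.01), Best3 (1.45 ± 0.11), CG10651 (1.45 ± 0.08), ACXB (1.23 ± 0.16) and CG32391 (0.91 ± 0.21). The others were AANATL2 (0.82 ± 0.05), Gpxl (0.68 ± 0.21), CG6106 (0.67 ± 0.14), d-cup (0.66 ± 0.19), CG31446 (0.60 ± 0.10) and Neto (0.43 ± 0.09), and CG12446, which did not pass the test (0.55 ± 0.40, adjusted p = 0.0905). With windows of 15 genes, 33 regions were called. Probes of neighbouring genes share positions in the table's printing order; with the trend along it removed, 58 regions were called and held 858 of the 923 genes.

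**Figure D2:**
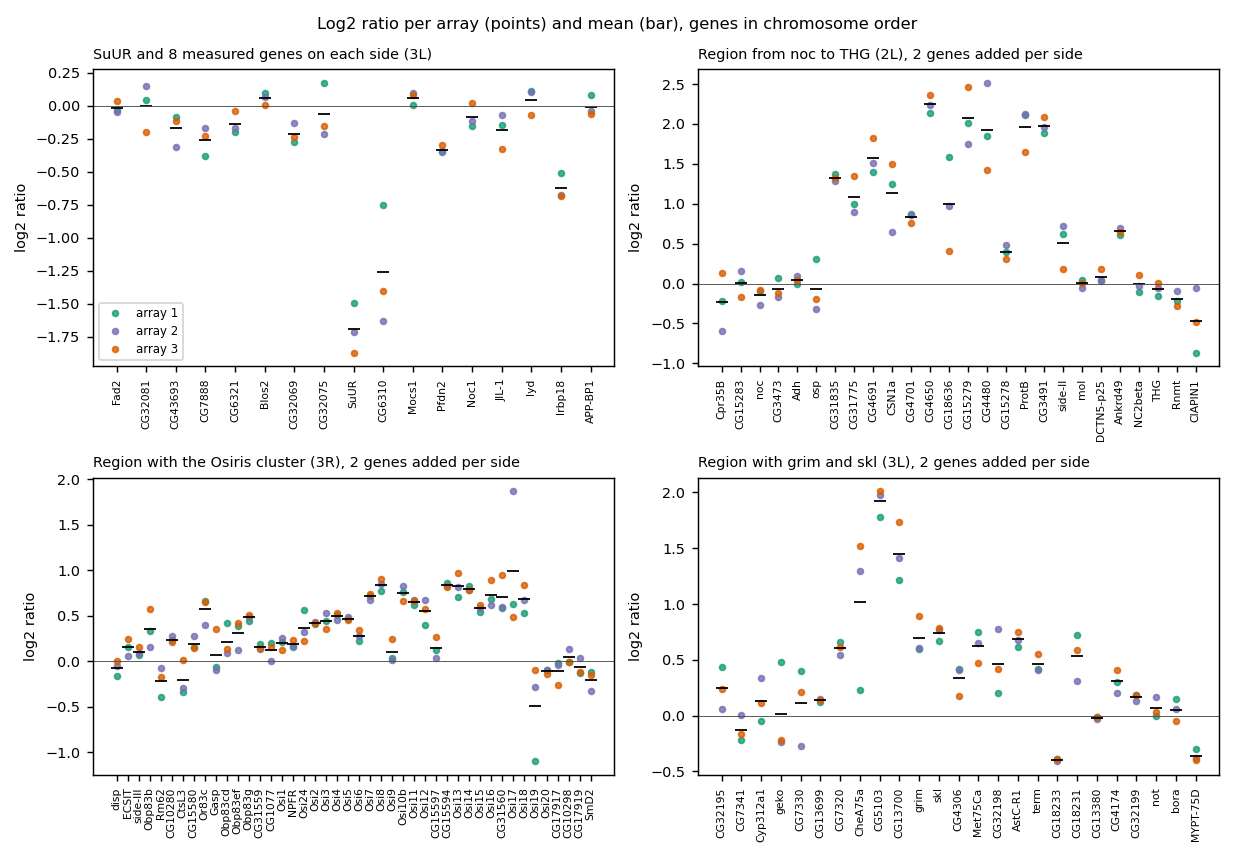
Log2 ratio per array (points) and mean of 3 arrays (bar) for genes in chromosome order around SuUR and in 3 called regions. SuUR (-1.69) and its neighbour CG6310 (-1.26) are the most negative of their panel, while the regions with CG4650, the Osiris genes and CG5103 hold runs of positive genes.

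Of 23 measured Osiris genes, a family mostly in a single cluster on 3R, 15 were positive in limma's test (18 adjusted over the list alone) and 0 negative, with a list median of 0.49. As a group they passed camera with a preset correlation (adjusted p = 6.92e-13) but not with an estimated correlation (adjusted p = 0.326). Osi8 had 0.84 ± 0.07, Osi13 0.83 ± 0.14 and Osi14 0.80 ± 0.02; Osi17 had the largest mean but did not pass (0.99 ± 0.76). Among landmark genes of 3 cytological regions, 5 of 9 were positive (5 adjusted over the list alone), with trn, a leucine-rich repeat protein, at 1.17 ± 0.19, skl at 0.74 ± 0.06, grim at 0.70 ± 0.17 and esg, a transcription factor, at 0.66 ± 0.17. In the Antennapedia complex, pb (0.26 ± 0.004) was the 1 of 8 genes that passed (1 adjusted over the list alone), and zen2 (0.26 ± 0.10), zen (0.21 ± 0.07) and Antp (-0.20 ± 0.08) did not.

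Of 124 chemosensory receptor genes, 25 were positive and 4 negative (28 and 10 adjusted over the list alone), led by Gr36c (2.14 ± 0.07), Or65b (1.34 ± 0.64), Or65a (1.30 ± 0.43) and Gr23a (1.22 ± 0.32); the list median was -0.001 and its mean 0.09. Among 33 developmental regulators, the T-box genes H15 (1.02 ± 0.11) and bi (0.65 ± 0.07) and the nuclear receptor gene knrl (0.62 ± 0.19) were the 3 positive genes and 1 was negative (3 and 1 adjusted over the list alone); Doc3 had -0.46 ± 0.40 and did not pass. Of 24 testis genes, 5 were positive and 1 negative (8 and 1 adjusted over the list alone), with the protamine gene ProtB at 1.96 ± 0.27, can at 0.71 ± 0.32 and Tpl94D at 0.52 ± 0.15, and Mst33A not passing (0.77 ± 0.58); the list median was -0.007 and its mean 0.16. Of 32 odorant-binding protein genes, 4 were positive and 1 negative (5 and 1 adjusted over the list alone), with Obp57c at 0.81 ± 0.27, Obp83g at 0.48 ± 0.03, Obp18a at 0.47 ± 0.19 and Obp56b, not passing, at -0.40 ± 0.54.

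By limma's camera with a preset correlation, the adjusted p was 6.92e-13 for Osiris genes, 0.000682 for chemosensory receptors, 0.000879 for landmark genes, 0.0275 for the Antennapedia complex and for developmental regulators, 0.0379 for testis genes and 0.0435 for odorant-binding proteins. None of these 7 calls held with an estimated correlation. The adjusted p was then 0.326 for Osiris genes, 0.602 for chemosensory receptors and testis genes, and 0.639 for landmark genes. It was 0.773 for the Antennapedia complex, developmental regulators and odorant-binding proteins. For testis genes the estimated correlation, -0.038, was below the preset 0.01, yet camera's unadjusted p rose from 0.0142 to 0.113. With 3 arrays this version also has few degrees of freedom, so the lost calls do not measure correlation between members alone. By permutation through rotation along the arms, chemosensory receptors (adjusted p = 0.0016), landmark genes (0.0485) and testis genes (0.0485) passed, and Osiris genes (0.0588), developmental regulators (0.173), odorant-binding proteins (0.248) and the Antennapedia complex (0.418) did not. The camera call of testis genes ended with the printing trend removed (adjusted p = 0.128), as did that of odorant-binding proteins (0.542), which was also lost without array 1 (0.115) or 3 (0.0747); that of developmental regulators ended without array 3 (0.192) and that of the Antennapedia complex without array 2 (0.061) or 3 (0.0584).

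The other 9 lists tested were not called. Of 29 ribosomal protein genes, 2 were positive and 3 negative, among them RpL22-like (1.09 ± 0.10) and RpS21 (-1.02 ± 0.34). Of 75 genes in the cytochrome P450 list, 3 were positive and 10 negative, as they were among the 73 left without the cyclophilin genes Cyp1 and Cyp40, which the name pattern had caught, with Cyp28d2 at -1.63 ± 0.28 and Cyp6t3 at -1.47 ± 0.07. Of 78 cuticle protein genes, 1 was positive and 5 negative, with Cpr67Fa2 at -1.10 ± 0.12 and Cpr67Fa1 at -0.87 ± 0.17. No gene passed (0 in limma's test) among 11 salivary gland glue and puff genes, with Sgs7 at -0.23 ± 0.13 and Eip63E at -0.72 ± 0.47, among 7 chorion genes, with Cp18 at -0.17 ± 0.21 and Cp7Fc at 0.12 ± 0.07, or among 10 genes of chromosome 4, with bt at -0.33 ± 0.23 and myo at -0.26 ± 0.14. Acp26Ab (-0.53 ± 0.24) was the 1 negative of 13 genes in the accessory gland list, or of 12 without the cuticle protein gene Acp1, beside Acp36DE (-0.36 ± 0.32), which did not pass. AttB (0.45 ± 0.08) was the 1 positive of 6 immune peptide genes, beside Mtk (-0.86 ± 0.86), and Parp1 (0.44 ± 0.09) was the 1 positive of 4 heterochromatin genes, beside d4 (-0.26 ± 0.12). Adjusted over the list alone, the positive and negative counts were 2 and 3 for ribosomal proteins, 3 and 13 for the cytochrome P450 list (with or without the cyclophilins), 0 and 5 for cuticle proteins, 1 and 1 for heterochromatin, 1 and 0 for immune peptides and 0 for the others. The Y-linked gene kl-5 had 0.89 ± 0.58 (adjusted p = 0.0727); no member of the white, bithorax complex or histone lists was measured under its name on all 3 arrays.

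**Figure D3:**
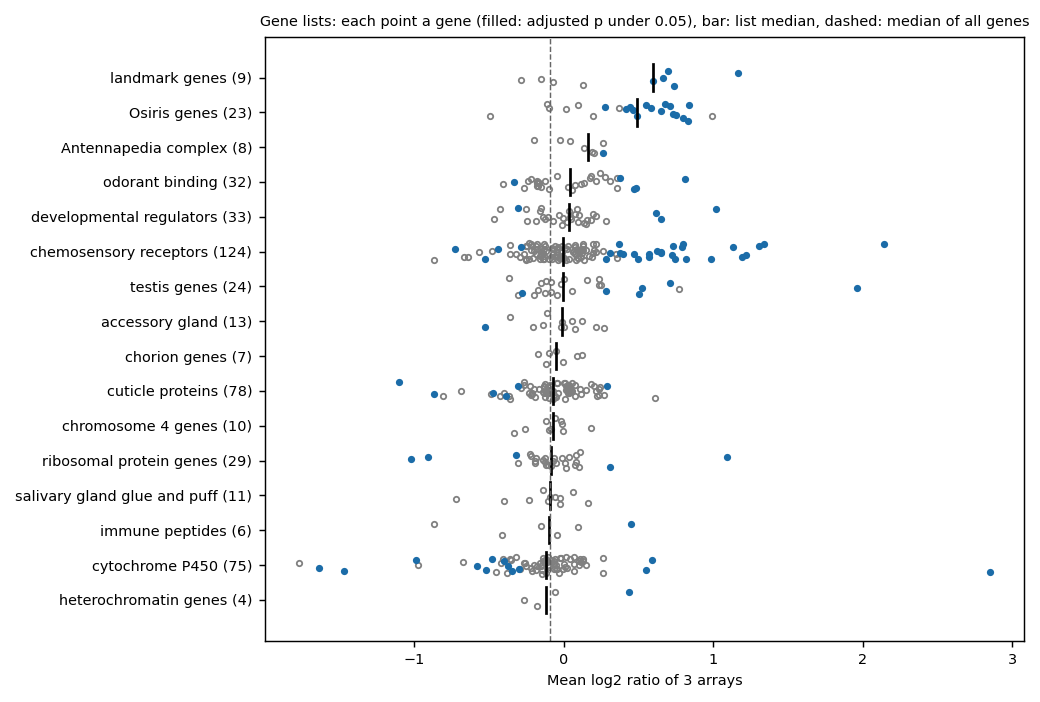
Mean log2 ratio of 3 arrays for each measured gene of 16 lists (filled points passed the adjusted threshold of 0.05), with the list median (bar) and the median of all genes (dashed line, -0.094). Osiris and landmark genes have medians of 0.49 and 0.60.

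The median ratio of X-linked genes was -0.02 ± 0.006, above -0.14 ± 0.02 on 2L, -0.12 ± 0.01 on 2R, -0.08 ± 0.01 on 3L and -0.06 ± 0.01 on 3R; chromosome 4 had -0.03 ± 0.06. X exceeded the large autosomal arms by 0.079 ± 0.011, in the same direction on all 3 arrays, which an exact sign-flip test cannot call since its smallest p is 0.25. With the trend along the printing order removed, the difference was 0.003 ± 0.013. That trend, from 0.05, 0.05 and 0.06 on arrays 1, 2 and 3 in row 14 to -0.30, -0.32 and -0.25 in row 32, goes with the place of the arms: from row 14 on, the median row was 15 for X, 19 for 3R, 21 for 3L, 23 for 2R and 26 for 2L. Chromosome 4, with 27, departs from this order.

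**Figure D4:**
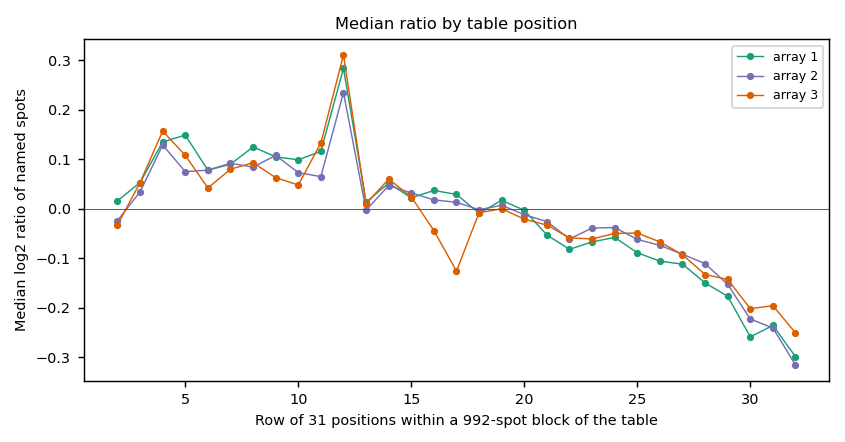
Median log2 ratio of named spots by row of 31 positions in the table's repeating blocks, for 3 arrays. The medians peak in row 12 at 0.28, 0.24 and 0.31 on arrays 1, 2 and 3. From row 14 on they mostly decline, to -0.30, -0.32 and -0.25 in row 32.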

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

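Probes without a gene name here, which are in none of the gene tests above but share in the median on which each array was centred, stood out as data outside the main measurement. Of 7326 such probes with values on all 3 arrays, 20.7% (1518) were at least 1.5-fold positive past limma's adjusted threshold, against 3.7% of 11266 named probes (420). Their median was 0.15 against -0.09, and 5.4% against 2.4% were at least 1.5-fold negative. Centring on named spots alone left 418 in place of 885 negative genes. The unnamed probes were not assigned to genes or places, and no biological explanation was tested.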

How the results depend on the processing

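Centring on named spots, removal of the printing trend and leaving out 3 list members of another gene family were chosen after seeing the data; the last left all 7 list calls in place. The counts of positive genes stayed within 1.5 times of 601 (all) and 352 (at least 1.5-fold) under other centring, scaling, averaging, missing-value and probe-level settings, and the number of positive regions did so in every setting but 1. Negative calls were less stable: against 885, there were 1847 without centring, 506 with centring on the mode, 418 on named spots and 211 with the printing trend removed, and against 231 at least 1.5-fold there were 399, 148 and 82 without centring, on named spots and with the trend removed. The limma treat test against 1.2-fold left 261 positive and 84 negative genes (83 at least 1.5-fold negative). Without moderation 4 positive and 1 negative genes passed, 2 and 0 of them at least 1.5-fold, since 3 arrays leave few degrees of freedom for a gene on its own. Leaving out 1 array gave 130 to 293 positive and 40 to 265 negative genes, with 130 to 277 and 40 to 254 at least 1.5-fold, partly because fewer arrays were left. Windows of 15 genes gave 33 positive regions and 1 negative region, window means 2 negative regions, and leaving out 1 array 0 to 3. The difference of X from autosomes moved to 0.003 with the printing trend removed; that setting takes out most differences between arms by construction. Of 7 lists, 0 passed with an estimated correlation, 3 by rotation and 2 by fry, which asks another question, and 4 to 6 when 1 array was left out. Testis genes and odorant-binding proteins also lost their call on named spots (adjusted p = 0.0538 and 0.0804) and with 2 of 3 arrays (0.0985 each), and under the planned centring on the mode (0.05, just above the threshold, and 0.0639). Except where stated, the cause was not tested.

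Some lists that were not called changed direction without being called. Camera's direction is relative to the other genes, so the list median need not change sign. That of ribosomal proteins was -0.087 in the main analysis and -0.032 with the printing trend removed. With the printing trend removed the direction changed for ribosomal proteins (camera adjusted p = 0.887) and for cuticle proteins, heterochromatin and immune peptides (0.974 each). On named spots it changed for chromosome 4 (0.998), and with 2 of 3 arrays, where a missing value took the gene's mean, for heterochromatin (0.99). By rotation it changed for chromosome 4 and cuticle proteins (0.9534) and immune peptides (0.8278). Fry tests a list against 0 and not against other genes. Its direction differed from camera's for accessory gland (0.567), cuticle proteins (0.0766), and chorion, heterochromatin and ribosomal proteins (0.355 each). With 1 array left out the adjusted p ranged from 0.821 to 0.974 for chromosome 4, from 0.754 to 0.997 for immune peptides and from 0.681 to 0.92 for ribosomal proteins. Among 108 genes with a reported value, Antp (0.051), Cp19 (0.105) and Cp7Fc (-0.036) changed sign with the printing trend removed, and Cp19 ranged from -0.262 to 0.137 with an array left out; none of the 3 had passed the test. Of the 108, 8 no longer passed with the printing trend removed, 4 on named spots and 1 each without centring, on the mode and with 2 of 3 arrays. The call of the gene Acp26Ab ended on the mode (adjusted p = 0.065), on named spots (0.0697), with the trend removed (0.142), with 2 of 3 arrays (0.0509) and without array 1 (0.125) or 2 (0.177). Without arrays 1, 2 and 3 in turn, 22, 42 and 18 of the 108 no longer passed. The alternative without dim spots was not run, as no signal column was used, and no array had its sign turned, since all pairs correlated positively. No paired analysis was possible because the 3 arrays form 1 group in which each array already compares both DNAs.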

Other observations

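The tests of far-apart print positions, the correlation at 1 print position, shares of genes with negative flanks, SD of called genes, tandem families, printing position for negative genes, testis placement, X genes of the second print set and the sign of the ratio were chosen after their results, or values close to them, had been seen. Apart from the regions, 3 strongly positive genes lay among neighbours without a positive median: the 4 genes flanking Cyp6a17 had a median of -0.14, those of Marf1 -0.34 and those of CG40006 -0.09. Of 24 testis genes, 8 lay in regions against 2.28 expected, and 0.0118 of rotations gave as many, although the p adjusted over the lists was 0.0629. Of 9 landmark genes 8 did (adjusted p = 0.008), of 23 Osiris genes 21 (0.0629), and of 8 Antennapedia complex genes 7 (0.276).

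The sign of the ratio is likely that of Su(UR)- over 4xSu(UR)+ DNA, so that positive regions would hold fewer copies in 4xSu(UR)+ glands. SuUR was negative (-1.69 ± 0.19), the direction that 4 doses in 4xSu(UR)+ DNA would give, though the labels set no expected size. CG31275, inside the bithorax complex, had a mean of 1.797 over 2 arrays. The check fixed beforehand used other genes of that complex and could not be run, so this remains a hypothesis resting on 1 gene on each side.

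Regions of positive ratio might come from the arrays and not the chromosomes. Adjacent genes at 1 print position correlated with r of 0.567, and those with probes more than 100 positions apart still with 0.28. On the array with the lowest value r was 0.304. These values argue against layout and single arrays as the whole cause. Pairs without a shared name root correlated with 0.418, but these were 9365 of all 9709 pairs. Neighbours with CG or CR names were never counted as sharing a root, so tandem families stay open. With the printing trend removed, adjacent genes correlated with 0.442, against 0.426 before, which argues against that trend as the source. Print position shared by neighbours otherwise stays open as a part of the correlation. The 2 separately printed probe sets were both above their medians in 29 of 41 regions (70.7%, exact 95% interval 54.5 to 83.9). This share lay between the limits set for either outcome. It is partly built in, since regions were called from both sets together. A biological difference in replication between the strains, which the design names, stays open and was not tested separately.

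Strongly negative genes may be in part technical. The genes flanking the 226 called at least 1.5-fold negative had a median of -0.189 (all genes -0.101), above the limit of -0.29 set for segments as the main cause. Still, 21.7% had flanks at or below it against 9.9% of all genes, and with the printing trend removed 10.6% against 2.3%, so segments stay open for a minority. The median SD between arrays was 2.758 times that of positive genes over all genes past 1.5-fold by their mean, called or not, and 1.553 times over called genes. After the printing trend was removed, 35.5% of the number called was left, 82 against 231 over all genes tested. That setting also recentres the named genes, and centring on named spots alone left 148, so the fall is not that of print position alone. In rows 29 to 32, 6.1% of probes were of such genes, against 1.2% in rows 14 to 28 and 1.7% in rows 1 to 13. Genes at least 1.5-fold positive also followed the rows, with 1.0%, 3.6% and 7.3% of probes in the same 3 parts. The strains differ by label in doses of Su(UR)+, but SuUR was not alone in repeating closely between arrays: bowl had -1.75 ± 0.05 and CG33013 -2.13 ± 0.17. Among the 15 most negative genes the SD ranged from 0.054 to 1.21, so noise cannot be read as the cause for each gene.

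The higher X median may follow print position, which could not be decided. Outside regions the X median was -0.004 ± 0.013 in the first print set and -0.129 ± 0.019 in the second. The large autosomal arms were also lower in the second set, with 2L at -0.113 ± 0.014 and -0.291 ± 0.056. Arm medians thus differ with the print set. Within each set X was still the highest, but the arms follow the print order there too. X and 2L genes printed in alternating runs differed by -0.018 ± 0.033, but X there belonged to the second print set and 2L to the first. X and 3R genes of the second set at neighbouring positions differed by 0.012 ± 0.025, with a 95% bootstrap interval over genes of -0.013 to 0.046, which holds both 0 and the difference of X and 3R outside regions, 0.036, so a different share of male and female larvae cannot be told apart from print position. Outside regions X still exceeded the autosomes by 0.077 ± 0.011, so more X genes in regions does not account for it. The limit set beforehand, which would have excluded a different share of the sexes because the autosomal arms themselves spanned 0.095, assumed arms free of a printing trend.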
